A study of Mus musculus with 23 samples.

How the data were processed

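RNA was extracted from skeletal muscle with a column kit that also retains small RNA, with a DNase step, and processed further by a sequencing provider, per the labels' protocols. Library layout, read length, aligner, tool versions and sequencing depth are not given in the sources used here. Per the labels' design text, alternative splicing was analysed with Whippet, which quantifies splicing events from reads aligned to a splice graph, and with rMATS, a junction-count method. Which of these tools gave which value is not stated in the file. Its columns for position, strand, difference and probability have the layout of a Whippet comparison, while its names for event types are those of rMATS. Adipose tissue, which the design text also names, was not analysed here. The genome build is mm10, per the submitters' processing notes.

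The authors deposited 1 table with 3 blocks, caloric restriction against ad libitum, intermittent fasting against ad libitum, and exercise against sedentary. Per the file headers, each row gives a gene, a position, a strand, an event type, the inclusion level of the control and of the treated group as a fraction from 0 to 1, their difference, a probability and a confidence class. The deposited difference is control minus treated, which was checked against the levels on every row (largest gap 1e-05). Differences are described here as treated against control, with the sign turned. Every listed event has an absolute difference of at least 0.2 and a probability of at least 0.9 in the authors' deposited table, so the lists hold called events only, and sizes are conditional on those limits. The probability is not a p-value. The confidence class is 1 or 2, with no statement of its meaning, and was used only to try class 1 alone. Levels are 1 value per group: how samples were combined is not stated, no error can be attached, and whether a single mouse carries a difference cannot be seen. Intervals in the text are exact (Clopper-Pearson) 95% binomial intervals over listed events and do not cover variation between mice.

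Groups were taken from the intervention label of each sample. A second label names every NZO sample as intermittent fasting and every C57BL/6J sample as exercise, controls included, and was read as the name of the experiment. The labels give no pairing of mice between groups. The lengths of all 15 distinct Neb exons, from 99 to 312 nucleotides, are divisible by 3 when both ends are counted, which fits positions counted from 1. Positions were read in that way because no header states how they are counted. Gene symbols were looked up in a RefSeq table of assembly GRCm38.p6, the same assembly as mm10: 219 of 221 symbols matched directly, 1 matched an older name and 1 did not match. All 251 distinct events of matched genes lie inside the span of their gene there, and 215 of the genes are protein-coding.

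The following was computed here with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and drawn with matplotlib 3.10.9. Events were counted per comparison, direction and type. The share with higher inclusion was tested with an exact two-sided binomial test, the shares of event types and of directions between lists with Fisher's exact test, and the median absolute difference with a two-sided permutation test of 100000 resamples. Adjustment was by Benjamini-Hochberg within each family. Events were called shared where position and type were identical. For the shared ad libitum control, 2000000 draws of unchanged groups with the sample numbers of the study and equal spread per sample were simulated. The tests were tried on simulated lists of the real sizes. For the direction test, with 80% of events in 1 direction, 100% of 200 draws were called in each comparison, and with an even division 3% to 5% were. Those simulated events were independent and free to go either way. Listed events can share a gene, and some could be listed in 1 direction only, so these rates need not hold for them. With no difference simulated, the test of type shares called 3% to 4.5% of 200 draws. The permutation test of size, tried with fewer resamples, called 5% to 7.5% of only 40 draws with no difference.

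Before the data were examined, 16 gene lists were fixed: sarcomere and Z-disc, excitation-contraction and calcium handling, RNA-binding proteins and spliceosome, circadian clock, insulin signalling and glucose metabolism, lipid metabolism and mitochondria, nutrient-sensing and stress kinases, autophagy and protein turnover, the dystrophin complex and neuromuscular junction, vesicle trafficking and microtubules, myogenic transcription, and markers of endothelial, immune, adipocyte, fibroblast, and Schwann, satellite and smooth muscle cells. Of these, 10 had no member with a listed event, among them calcium handling, lipid metabolism, nutrient sensing, autophagy, myogenic transcription and all 5 lists of other cell types. An empty list says only that none of its chosen members was listed. Other genes of the same process can have events: Acsl4, a long-chain acyl-CoA synthetase with a listed event, was not in the lipid list. A direction test was planned for a list with 6 or more events, which only the sarcomere list under caloric restriction reached. The genes named are those of the 10 largest absolute differences per comparison, every listed member of a fixed list, every gene in all 3 comparisons, and up to 10 genes in 2 of them by mean absolute difference. Of the genes this rule gives, 2 are not reported here. Genes named outside that rule are said to be so. The settings varied were stricter limits on size and probability, genes in place of events, 1 event per gene, skipped exons only, other definitions of a shared event, and the mean in place of the median. A limma fit on inclusion per sample and leaving out replicates were planned only for values per sample and were not run.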

Results

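Alternative splicing was measured by RNA sequencing in skeletal muscle of 23 male mice. NZO mice, a polygenic strain prone to obesity and diabetes, were fed ad libitum (5 samples), kept on intermittent fasting (5 samples) or kept on caloric restriction (3 samples). C57BL/6J mice, a common inbred strain without diabetes, were sedentary (5 samples) or exercised (5 samples). The comparisons ask which splicing events differ in muscle after each intervention, with caloric restriction and intermittent fasting set against the same ad libitum mice and exercise set against sedentary mice. The authors' deposited table lists 265 events in 221 genes, of 252 distinct positions and types. Each event has 1 inclusion level per group (PSI, percent spliced in, on a scale from 0 to 1), which is the authors' own value for that group. No level per mouse was used here, so no standard deviation can be given for any level, and the sequencing depth behind each level is unknown. The evidence for an event is the probability of a difference in the authors' deposited table, which is at least 0.9 for every event, together with an absolute difference of at least 0.2. Positions are mm10 coordinates. They were read as counted from 1 with both ends included, which was inferred from the lengths of the Neb exons. Skipped exon, retained intron and alternative splice site are the authors' event types, and a listed stretch need not be a whole exon or intron. In Eda, named only as an example, a skipped exon (chromosome X, 100395675 to 100395813) directly adjoins a 5' splice site stretch (100395814 to 100395830). Whether a stretch is coding or untranslated was not determined here.

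Caloric restriction in NZO muscle was listed with 114 events in 102 genes. Of these, 60 had higher and 54 had lower inclusion under caloric restriction than under ad libitum feeding. An alternative 3' splice site of Acsl4, a long-chain acyl-CoA synthetase (chromosome X, 142351616 to 142351618), had a level of 0.290 ad libitum and 0.921 under caloric restriction. A retained intron of Abcc8, the sulfonylurea receptor subunit of a potassium channel, had levels of 0.338 and 0.899 in the same order. The largest difference of the comparison was in the opposite direction: a stretch of 3 nucleotides at a 3' splice site of Mindy2, a deubiquitinase (chromosome 9, 70605287 to 70605289), was included at 0.947 ad libitum and at 0.294 under caloric restriction.

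Other events among the 10 with the largest differences under caloric restriction also ran both ways. Inclusion was higher for a retained intron of Sp110, a nuclear body protein (0.163 ad libitum, 0.785 under caloric restriction), for an alternative 5' splice site of Rbm10, an RNA-binding regulator of splicing (0.303 and 0.893), for a skipped exon of Lrrc51 (0.170 and 0.759) and for a skipped exon of the predicted gene Gm12002 (0.192 and 0.755). It was lower for a skipped exon of the pseudogene Ppp4r1l-ps (0.821 and 0.189) and for a 3-nucleotide 3' splice site event of Hectd2, a ubiquitin ligase (0.710 and 0.158). Reads of a pseudogene can be shared with its parent gene, so the Ppp4r1l-ps level is uncertain.

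The feature of the caloric restriction list with the most events in a single gene was Neb, which encodes nebulin, the giant protein that runs along the thin filament of the sarcomere. The list held 9 skipped exons of Neb, and all 9 had higher inclusion under caloric restriction. Their levels were between 0.000324 and 0.0646 ad libitum and between 0.235 and 0.465 under caloric restriction. The direction test fixed for such a list gave p = 0.00391 (9 of 9, exact two-sided binomial test), but it carries no weight here: every listed difference is at least 0.2, so an exon with so low an ad libitum level could only be listed as higher, and exons of 1 gene are not independent. At a minimum difference of 0.3, 2 of the 9 exons were left. Nebulin is built of repeats, and whether reads are shared among its exons was not determined here, so the level of any single exon is uncertain.

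Of the 700 distinct genes in the 16 lists fixed before the data were examined, 6 had an event under caloric restriction, of which 5 are described. Besides Neb from the sarcomere list, 2 came from the list of RNA-binding and spliceosome proteins, and both had higher inclusion: a retained intron of Prpf4b, a kinase of the spliceosome (0.499 ad libitum, 0.894 under caloric restriction), and an alternative 3' splice site of Tia1, an RNA-binding splicing factor (0.341 and 0.721). A skipped exon of Dtnb, the dystrophin-associated protein beta-dystrobrevin, had higher inclusion (0.639 and 0.906), and a skipped exon of Gopc, a Golgi trafficking protein, had lower inclusion (0.774 and 0.380). The table holds called events only, so whether any list was over-represented could not be tested.

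Over all events of the comparison, 52.6% had higher inclusion under caloric restriction (95% exact confidence interval 43.1% to 62.1%), which did not differ from an even division (exact two-sided binomial test, p = 0.640, 0.906 after Benjamini-Hochberg adjustment over the 3 comparisons). The share was 48.6% without Neb and 48.0% with 1 event per gene, on the other side of an even division in both cases, and 58.3% of the 48 events with a probability of at least 0.95.

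Intermittent fasting in NZO muscle was listed with 79 events in 73 genes, of which 31 had higher and 48 had lower inclusion than under ad libitum feeding. The largest difference of the whole table was a skipped exon of Lss, lanosterol synthase of the cholesterol pathway (chromosome 10, 76537569 to 76537663), with a level of 0.887 ad libitum and 0.203 under intermittent fasting. Sh2b2, an adaptor protein of the insulin receptor, had lower inclusion of a 4-nucleotide stretch at a 5' splice site (0.930 and 0.366; chromosome 5, 136244629 to 136244632). Dtnb had 2 listed exons that went in opposite directions: the exon at chromosome 12, 3773551 to 3773640, had levels of 0.208 and 0.792, and the exon at 3774570 to 3774610 had levels of 0.731 and 0.241.

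Among the rest of the 10 largest differences under intermittent fasting, lower inclusion was listed for Plppr2, a phospholipid phosphatase-related membrane protein (0.890 ad libitum, 0.257 under fasting), for Cwc22, a spliceosome-associated protein (0.860 and 0.243), for Tesc, a calcium-binding protein (0.672 and 0.106), for Lclat1, a lysocardiolipin acyltransferase (0.688 and 0.128), and for Cdca4 (0.796 and 0.242). Higher inclusion was listed for 3' splice site events of Sufu, a suppressor of Hedgehog signalling (0.112 and 0.704), and of Nat14 (0.340 and 0.927). The fixed lists again gave 6 genes. Neb had 2 exons, both higher under fasting, at levels of 0.000334 and 0.229 for one and 0.244 and 0.544 for the other. Skipped exons of Ank1, the membrane skeleton protein ankyrin 1 (0.925 and 0.617), and Gopc (0.775 and 0.331) and a retained intron of Prpf39, a spliceosome component (0.600 and 0.255), had lower inclusion.

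Of the fasting events, 39.2% had higher inclusion (95% exact confidence interval 28.4% to 50.9%). The division did not pass the test (exact two-sided binomial test, p = 0.0712, 0.213 after Benjamini-Hochberg adjustment over 3 comparisons). Among the 14 alternative 5' splice site events of this comparison, 3 were higher and 11 lower (exact binomial test, p = 0.0574, 0.688 after adjustment over 12 tests by type and comparison). Fasting events with an ad libitum level within 0.2 of 0 or 1 could be listed in 1 direction only. How far such starting levels shape these shares was not tested.

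Exercise in C57BL/6J muscle was listed with 72 events in 67 genes, 35 with higher and 37 with lower inclusion than in sedentary muscle. Per1, a core repressor of the circadian clock, was the only member of the clock list in any of the comparisons. Its retained intron (chromosome 11, 69105624 to 69106452) had a level of 0.208 in sedentary and 0.549 in exercised muscle. Neb was the only other listed gene that belongs to a fixed list. It had 5 skipped exons, all higher after exercise, with levels between 0.0519 and 0.0743 in sedentary and between 0.261 and 0.420 in exercised muscle.

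Retained introns made up 5 of the 10 largest differences after exercise. Inclusion was higher in exercised muscle for introns of 4930503L19Rik (0.184 sedentary, 0.816 exercised), Herc6, a HECT-domain protein (0.0947 and 0.641), Sfxn2, a mitochondrial sideroflexin (0.112 and 0.624), and Ndor1, a diflavin oxidoreductase (0.117 and 0.607), and lower for an intron of Reep4 (0.650 and 0.167). A skipped exon of Abl2, a non-receptor tyrosine kinase, had lower inclusion (0.715 and 0.210). Splice site events of Lancl2 (0.305 and 0.820), Sgpl1, the sphingosine-1-phosphate lyase (0.439 and 0.929), Fbxw17 (0.121 and 0.601) and Fam122b (0.0880 and 0.563) had higher inclusion. Over all exercise events 48.6% were higher (95% exact confidence interval 36.7% to 60.7%; exact two-sided binomial test, p = 0.906 before and after adjustment). The share lay above an even division under stricter limits, at 65.2% of 23 events with a probability of at least 0.95 and 51.2% of 41 events with an absolute difference of at least 0.3. Neither passed the exact binomial test (p = 0.210, 0.468 after adjustment, for the first). Events with a sedentary level within 0.2 of 0 or 1 could again be listed in 1 direction only.

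**Figure D1:**
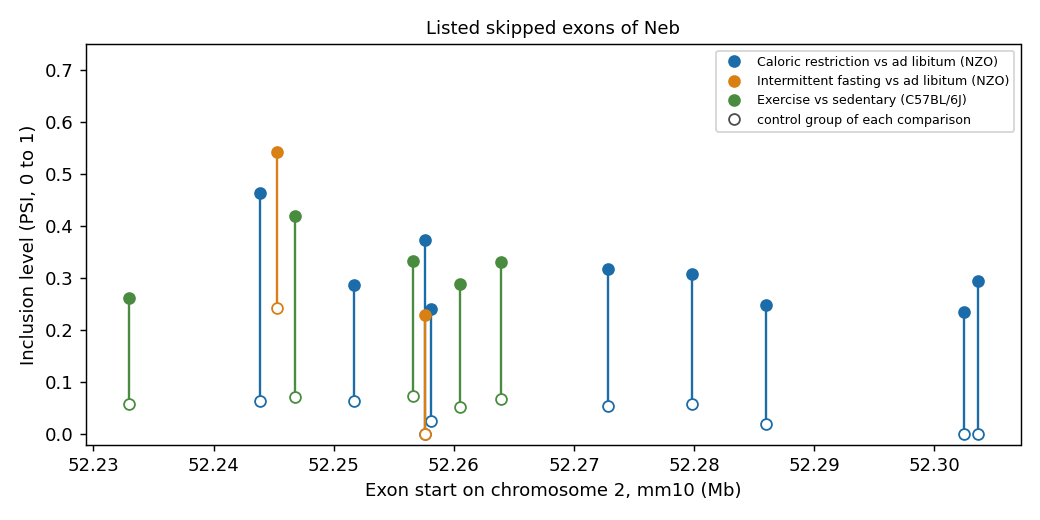
Inclusion level (PSI, 0 to 1, vertical axis) of each listed skipped exon of Neb by its start on chromosome 2 in mm10 (horizontal axis, Mb), with open circles for the control group, filled circles for the treated group and 1 colour per comparison. All 16 listings run upwards from control to treated, and apart from 1 fasting exon at 0.244 every control level is at or below 0.0743.

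No difference between the 3 lists in the kinds of events passed a test. Skipped exons were 52.6% of the events under caloric restriction, 46.8% under intermittent fasting and 48.6% after exercise. Retained introns were 22 of 114, 15 of 79 and 18 of 72 events in the same order, alternative 3' splice sites 18.4%, 16.5% and 15.3%, and alternative 5' splice sites 9.65%, 17.7% and 11.1%. None of the 12 comparisons of a type between a pair of lists passed Fisher's exact test before or after adjustment (smallest unadjusted p = 0.127, for alternative 5' splice sites under caloric restriction against fasting; adjusted p = 1). The share of events with higher inclusion did not differ between lists either, with the smallest p for caloric restriction against fasting (Fisher's exact test, two-sided, p = 0.0790, 0.237 after adjustment over 3 tests). The median absolute difference was 0.352 under caloric restriction, 0.355 under fasting and 0.315 after exercise. The difference of 0.0405 between fasting and exercise gave p = 0.0490 in a two-sided permutation test with 100000 resamples, and 0.147 after adjustment over the 3 pairs. With 1 event per gene this difference was 0.0223 (permutation test, unadjusted p = 0.297), and without Neb it was 0.0233, also short of the threshold before adjustment. The difference in means was 0.0385 (permutation test, unadjusted p = 0.0312, adjusted p = 0.0935). These tests describe the listed events, which had already passed the authors' limits, and events of 1 gene are not independent.

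**Figure D2:**
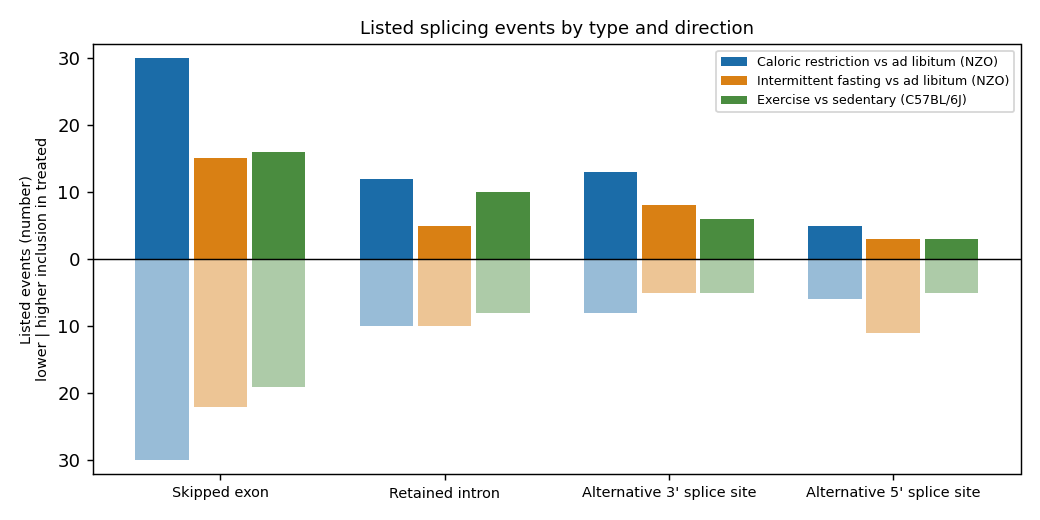
Number of listed events (vertical axis) by event type (horizontal axis) and comparison (colour), with solid bars above 0 for higher and pale bars below 0 for lower inclusion in the treated group. Skipped exons are the most frequent type in each comparison, with 30 higher and 30 lower under caloric restriction.

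The dietary lists had 14 genes in common, and 10 events were listed in both at the same position and type. All 10 went in the same direction. Inclusion was lower under both diets for Rnf111, a SUMO-targeted ubiquitin ligase (0.712 ad libitum, 0.223 under caloric restriction, 0.251 under fasting), for Exoc2, a subunit of the exocyst (0.565, 0.116 and 0.214), for Hmgn3, a nucleosome-binding protein (0.715, 0.239 and 0.368), and for Cwc22, Hectd2, Gopc, Pcgf5 and Stap2, of which Pcgf5 and Stap2 are named only to complete the 10. It was higher under both diets for a retained intron of Zfp446, a zinc finger protein (0.306, 0.817 and 0.688), and for a Neb exon. The caloric restriction and fasting levels at these events lay at most 0.144 apart. The 2 comparisons share the ad libitum mice, whose level differed by at most 0.0053 between the blocks of the table. Agreement in 10 of 10 events gives p = 0.00195 in an exact two-sided binomial test, but that test takes the comparisons to be independent. The test also takes each event as free to go either way. The Neb exon (0.000326 ad libitum) and Cwc22 (0.860 ad libitum) were not, since every listed difference is at least 0.2. When unchanged groups of the same sizes were simulated against 1 shared control group, the direction was the same in 91.0% of the draws past 1 standard error in both comparisons and in 99.7% of those past 2. In this simulation, shared controls alone thus gave nearly the same share of matching directions as seen here. It used unbounded levels and limits in standard errors, not the authors' limits on difference and probability, so its percentages are only a guide. How many shared events chance would give was not computed, because the events tested and not called were not used here.

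**Figure D3:**
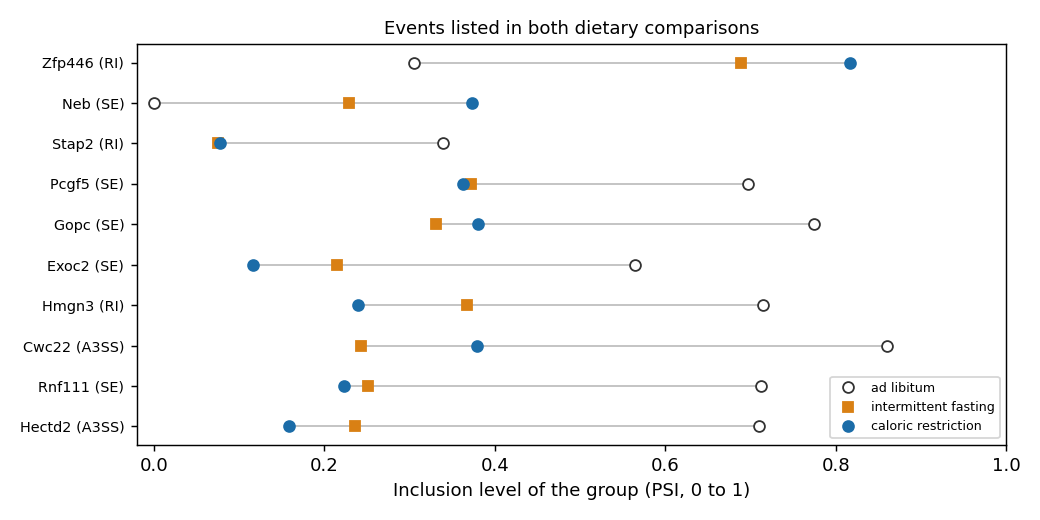
Inclusion level (PSI, 0 to 1, horizontal axis) of the 10 events listed in both dietary comparisons, with an open circle for the ad libitum group, a square for intermittent fasting and a filled circle for caloric restriction. Both diets lie on the same side of the ad libitum level in each row, lower for 8 events and higher for Zfp446 and Neb.

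The other genes found under both diets had different events. Ppp4r1l-ps had a second exon with lower inclusion under fasting (0.583 ad libitum, 0.108 under fasting). Cep295, a centrosomal protein, had a skipped exon under caloric restriction (0.595 and 0.905) and a retained intron under fasting (0.219 and 0.763), both with higher inclusion. Ldb2, a LIM-domain-binding transcription cofactor, had higher inclusion of an exon under caloric restriction (0.478 and 0.880) and lower inclusion of a 5' splice site stretch under fasting (0.726 and 0.309).

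Exercise, measured in another strain with its own controls, had 7 genes in common with caloric restriction and 3 with fasting. Neb, Hectd2 and Zfp446 were listed in all 3 comparisons. The retained intron of Zfp446 (chromosome 7, 12981928 to 12982118) was the 1 event found in all 3, and it had higher inclusion in each treated group, with 0.503 in sedentary and 0.880 in exercised muscle. A skipped exon of Hectd2 (chromosome 19, 36597077 to 36597186) was listed in both strains, with levels of 0.668 ad libitum and 0.907 under caloric restriction, and 0.655 sedentary and 0.905 exercised. Hivep2, a zinc finger transcription factor, had lower inclusion of different exons under caloric restriction (0.786 and 0.444) and after exercise (0.583 and 0.183). A 5' splice site event of Parp9, named because it was the only shared event with opposite directions and so chosen after its values were seen, had higher inclusion under caloric restriction (0.503 and 0.779) and lower inclusion after exercise (0.804 and 0.496). From a sedentary level of 0.804 it could only be listed as lower, since every listed difference is at least 0.2. Its probabilities, 0.904 and 0.911, lay close to the authors' limit. With 3 events shared between caloric restriction and exercise, the smallest p the exact binomial test can give is 0.25, so their directions could not be tested, and the difference in Parp9 was not tested.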

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

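No paired analysis was possible because the table gives 1 level per group and the labels pair no mice. For the same reason no mouse could be left out, and how far any event rests on a single animal stays unknown. The planned size limits of 0.15 and 0.2, the exclusion of first-exon, last-exon and tandem events and the exclusion of events without a single gene symbol removed nothing, so they say nothing about stability. A choice between callers was not run, because the table names none. The limits of 0.3 on size and 0.99 on probability, class 1 alone and leaving out Neb were chosen after seeing the data, as was 0.95 on probability for event types, shared genes and fixed lists. A minimum probability of 0.95 left 48 events under caloric restriction, 28 under fasting and 23 after exercise, and 0.99 left 15, 6 and 3; many events thus lie close to the authors' limit. A minimum size of 0.3 left 41 exercise events, and left 77 and 58 in the dietary lists. The share with higher inclusion passed no test under any setting once adjusted. Under caloric restriction it turned to 46.8% at a size of 0.3, to 48.6% without Neb and to 48.0% with 1 event per gene, but was 58.3% at a probability of 0.95 and 73.3% at 0.99; after exercise it turned to 65.2% at a probability of 0.95, 100% (3 of 3 events) at 0.99, 51.2% at a size of 0.3 and 53.2% in class 1. The fasting share stayed below an even division under each setting. Its unadjusted exact binomial p was 0.0247 at a size of 0.3 and 0.0395 without Neb, with adjusted values above the threshold. It was 0.851 at a probability of 0.95 (46.4%) and 0.324 for skipped exons only (40.5%). Events with a control level within 0.2 of 0 or 1 could be listed in 1 direction only. The stable side of the fasting share may therefore reflect starting levels, which was not tested. No event type differed between lists after adjustment under any setting run; at 0.99, 1 of 12 tests passed unadjusted. Caloric restriction and fasting shared 7 genes at a probability of 0.95, 2 at 0.99 and 9 in class 1. Caloric restriction and exercise shared 3 events, by identical or overlapping position, and 3 genes at a size of 0.3, 1 at 0.95 and 0 at 0.99. Fasting and exercise shared 1 event by either definition, 1 gene at 0.95, 1 at 0.3, 1 in class 1 and 0 at 0.99. The difference in median size between caloric restriction and fasting turned from -0.0029 to 0.00175 with 1 event per gene, and no difference in size passed after adjustment. The difference between fasting and exercise, 0.0405 with an unadjusted permutation p of 0.0490, was 0.0223 (permutation p = 0.297) with 1 event per gene and 0.0233 without Neb, both short of the threshold before adjustment, and 0.0385 between means (permutation p = 0.0312, 0.0935 after adjustment). Events of fixed-list members under caloric restriction numbered 5 at a size of 0.3, 5 at 0.99, 5 without Neb and 6 as genes; under fasting 4 at 0.95 and 2 at 0.99; after exercise 3 at 0.95, 2 at 0.3, 0 at 0.99, 1 without Neb and 2 as genes. The 9 Neb exons under caloric restriction numbered 8 at 0.95, 5 at 0.99 and 2 at a size of 0.3; the 2 under fasting 1, 1 and 0; and the 5 after exercise 2, 0 and 1. The cause of these changes was not tested beyond the smaller number of events.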

Other observations

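Everything in this part was looked at only after the results were seen, apart from the test on levels far from 0.5, for which only the choice to leave out Neb came later. Genes of the sterol pathway other than Lss were also listed, picked by eye and without a test of enrichment. Those named here had higher inclusion, whereas the Lss exon had lower inclusion, so they have no common direction. Under fasting, a skipped exon of Mvk, mevalonate kinase, had levels of 0.450 ad libitum and 0.792 under fasting. Under caloric restriction, a 3' splice site event of Tm7sf2, a sterol reductase, had levels of 0.453 and 0.715. Outside the sterol pathway, and likewise picked by eye, a retained intron of Noct, a gene with a circadian rhythm in many tissues, had levels of 0.224 ad libitum and 0.647 under caloric restriction. None of Mvk, Tm7sf2 and Noct was in both dietary lists.

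Short tandem splice acceptors were frequent among the listed events. Of 43 distinct alternative 3' splice site events, 23 covered exactly 3 nucleotides, among them those of Mindy2, Acsl4, Hectd2, Cwc22, Sufu and Nat14. The share among alternative 3' splice sites that were not listed was not measured here, so this may hold for such sites in general. Within a coding sequence, inclusion or omission of such a stretch adds or removes 1 codon or exchanges residues without a shift of the frame. Reads that tell such sites apart differ by 3 bases at a junction, and the depth at these junctions is unknown.

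The first pattern is Neb, with 15 distinct exons listed and each higher in the treated group, 10 in NZO and 5 different ones in C57BL/6J mice. An exact two-sided binomial test of 15 of 15 gives p = 6.1e-05, but it excludes nothing about chance: 14 of the 15 exons had a control level below the smallest listed difference and so could only be listed as higher. Exons of 1 transcript can also move together in a single mouse or library, and the dietary comparisons share the ad libitum mice, so chance stays open. Reads shared between repeats of Neb may also contribute: 12 of the 15 exons have the same length as another listed Neb exon, which decides nothing, since neither sequences nor unlisted Neb exons were compared here. A change in Neb splicing with diet and exercise is a hypothesis that remains untested.

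The second pattern is the longer list under caloric restriction, 1.44 times that of fasting, from 3 treated mice against 5. Neb alone does not account for it, since the ratio without Neb was 1.36 (105 against 77 events). Noisier group levels from fewer mice could lengthen a list. If so, caloric restriction levels should lie farther from 0.5 than their controls more often than fasting levels do; they did in 47.6% of events against 50.6% without Neb (Fisher's exact test, two-sided, p = 0.764) and in 43.9% against 49.4% with Neb (p = 0.466), which decides nothing. After exercise, with 5 treated samples, the share was higher than in either dietary list, at 61.2% without Neb and 56.9% with Neb. That list comes from another strain with its own controls and starting levels, so it cannot show how this measure depends on the number of treated mice. Group size, depth and a stronger effect of caloric restriction therefore cannot be told apart in this table.

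The third pattern is the frame, since of 126 distinct skipped exons 74 (58.7%) had lengths divisible by 3, against 1 in 3 for random lengths. All lengths in this paragraph are those of the listed stretches, which need not be whole exons or introns. The Neb exons are no evidence for it, since positions were read as counted from 1 because that makes all their lengths divisible by 3. Without them the share was 53.2% (59 of 111, 95% exact interval 43.4% to 62.7%, exact binomial test against 1 in 3, p = 1.87e-05). With Neb included, such lengths were 42 of 60 under caloric restriction, 19 of 37 under fasting and 17 of 35 after exercise. Differences between the lists in this share were not tested. Retained introns had a share of 31.4% (16 of 51), below that of skipped exons without Neb (Fisher's exact test, p = 0.0112), so these types differed. A like pattern in the splice site events was not shown. Alternative 3' splice sites had a share of 67.4% (29 of 43). Of these 29, 23 were the 3-nucleotide stretches, whose length is divisible by 3 by definition. Alternative 5' splice sites had a share of 43.8% (14 of 32), with a 95% exact interval that includes 1 in 3. A candidate explanation is that transcripts which keep their frame escape decay and are seen more often, but the share among skippable exons that did not change was not measured here, so this pattern may hold for cassette exons in general and not only for those listed.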
